A study of Caenorhabditis elegans with 14 samples.

How the data were processed

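The data were single-end enhanced CLIP (seCLIP) libraries of Caenorhabditis elegans. In this assay RNA is crosslinked to protein with ultraviolet light, a protein is immunoprecipitated, and the RNA that stays attached is sequenced beside an input library of the same lysate. The protein was EIF-3.G, a subunit of the translation initiation factor eIF3 that carries an RNA recognition motif. It was expressed with a 3xFLAG tag from a promoter active in cholinergic motor neurons and precipitated with an anti-FLAG antibody. Per the labels' protocols, worms of mixed stages were crosslinked at 3 kJ/m2 and sonicated. There were 14 samples, a CLIP and an input library for each of 7 experiments. The intact protein, EIF-3.G(+), the substitution EIF-3.G(C130Y) and the form without the RNA recognition motif, EIF-3.G(ΔRRM), had 2 CLIP libraries each, and the wild type N2 strain without a transgene had 1. The (+) and ΔRRM transgenes were in worms carrying acr-2(n2420), and the C130Y transgene was in worms carrying acr-2(n2420) and the same substitution in eif-3.G itself. The no-transgene worms carried neither allele, so transgene and strain background changed together in that comparison and in the comparison with C130Y. The source label of the no-transgene library names an IgG control while its antibody label names anti-FLAG, and the library is called the no-transgene library here. Nothing in the labels says whether the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

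The authors deposited 1 list of peaks per CLIP library. Peaks were called per library and not on pooled libraries, as the lists show. Coordinates were in build ce10, and reads had passed cutadapt 1.9.1, STAR 2.4.0i and SAMtools 1.4.1, per the submitters' processing notes. The peak caller is not given in the sources used here. Each deposited peak has a log2 enrichment of CLIP over its own input and a −log10 p-value. Both are the authors' values and were used to describe, rank and filter peaks within a list, and libraries were compared by overlap. The deposited −log10 p-values reached a cap of 400 and were 0 at all peaks with a log2 below 0. No peaks of a library overlapped on a strand, but some abutted, and between 60 and 489 abutting pairs per library had the same values in both pieces.

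The lists hold no read numbers. The log2 and −log10 p-values of low peaks fell on the steps that whole reads give, so the reads were recovered from them, a step chosen after the values were seen. The log2 value was taken as the ratio of CLIP reads to input reads, with at least 1 input read, each divided by its library total. The p-value was taken as Fisher's exact test where a read number was below 5 and as a Yates-corrected chi-square test otherwise. This model gave the deposited −log10 p-value, within 0.001 or 1%, for 94.3% to 99.2% of the peaks with a p-value in each library. Among enriched peaks it did so for 80.1% to 95.9%, and most of the rest were at the cap. On simulated data with 5000 peaks for each of 3 libraries, 51, 513 and 322 peaks were enriched, and the read numbers of 100% of these were recovered. The simulated p-values came from the same model and had no cap, so recovery at the cap was not tested. Read numbers of peaks at the cap are lower bounds. The totals are those the authors' software divided by, and reads were not analysed here.

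A peak was called enriched at a log2 enrichment of at least 1 and a −log10 p-value of at least 3. Enriched peaks of all 7 libraries that overlapped by at least 1 nt on the same strand were merged into regions, which gave 2738 regions. Within 5 kb of one another these formed 1480 loci. A region was reproducible in a genotype when both of its libraries had an enriched peak there, and absent from a library that had none. An absent region may still hold a listed peak below the thresholds. The number with such a peak of a log2 above 0 is given for the main sets of absent regions. It was not counted for the regions shared by (+) and C130Y and absent from the controls. The step that makes the sets was tested on 1300 simulated regions, where 0 of 9 sets had a wrong number. Overlaps were set beside the number expected for independent lists, the product of both list lengths divided by 2738, which takes as its background the regions enriched in at least 1 library. Numbers of enriched peaks were compared by exact two-sided permutation of the libraries on the log2 scale. With 2 libraries per genotype there are 6 arrangements and p cannot go below 0.333. Library similarity was the Jaccard index, the shared regions over the union, and its mean within genotypes minus that between genotypes was ranked among the 15 ways to split the 6 tagged libraries into pairs, where p cannot go below 0.0667. Shares have 95% Wilson intervals, which cover counting error only.

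The regions named were chosen by a rule fixed before the data were examined. For each of 5 sets, the 10 regions with the highest value of the lower replicate were taken. These were the (+) regions absent from ΔRRM and no-transgene, the ΔRRM regions absent from (+), the regions reproducible in both (+) and C130Y and absent from ΔRRM and no-transgene, the (+) regions absent from C130Y, and the C130Y regions absent from (+). The 50 entries are 42 distinct regions in 37 loci, since some regions belong to more than 1 set and some abut. Coordinates are ce10, counted from 1. Where several listed peaks of a library fell in a region, the highest is given. Many of the highest log2 values rest on 1 to 3 input reads, where a single read more lowers the log2 markedly.

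The annotation at hand was of a later build, WBcel235. The most frequent offset between peak starts and annotated exon starts ranged from −7 to 101 nt across 103 windows of 1 Mb and was 0 in 4 of them, so the builds were not mixed. Gene names, the share of peaks in untranslated and coding sequence, gene list tests and the length and GC content of 5′ untranslated regions, all planned for the case of matching builds, were not run, and regions are given by position.

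CLIP totals recovered ranged from 0.192 to 1.72 M reads, so libraries were also compared after random thinning of the recovered reads. All 6 tagged libraries were thinned 100 times to the lowest tagged totals, 0.544 M CLIP and 1.14 M input reads, or to the no-transgene totals, and the sets were recomputed on 20 of the thinnings to the tagged totals. The deposited peak positions were kept, and peaks were not called anew on thinned reads. The number of (+) regions that the other libraries would miss was simulated 1000 times from the (+) read shares at their depths. Other log2 and p minimums, other overlaps, a stricter meaning of absence, leaving out each library and a replicate block were tried, and their effect is given with the additional observations. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.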

Results

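RNA crosslinked to 3xFLAG-tagged EIF-3.G in cholinergic motor neurons was profiled for the intact protein (+), for the C130Y substitution and for a form without the RNA recognition motif (ΔRRM), each in 2 CLIP libraries, beside 1 library from worms without a transgene. Each library was divided by its own input. The 2 (+) lists held 34441 and 25547 peaks, the C130Y lists 26612 and 36324, the ΔRRM lists 11021 and 21441 and the no-transgene list 7170. Recovered CLIP totals were 1.70 and 1.57 M reads for (+), 1.21 and 1.72 M for C130Y, 0.544 and 0.893 M for ΔRRM and 0.192 M without a transgene. Input totals were 1.14 and 1.29 M, 3.03 and 1.67 M, 1.55 and 1.31 M, and 0.429 M reads in the same order. The median enriched peak rested on 107 and 92 CLIP reads in (+), 43 and 87.5 in C130Y, 20 and 37 in ΔRRM and 29 without a transgene.

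The first comparison asked how many peaks each library gave above input. The ΔRRM libraries had 1767 and 1146 enriched peaks, the C130Y libraries 1181 and 958 and the (+) libraries 640 and 651, and the no-transgene library had 615. The ΔRRM mean was 1456.5 ± 439 (SD, n = 2) against 645.5 ± 7.78 (SD, n = 2) in (+), a 2.20-fold difference of geometric means. For C130Y, 1069.5 ± 158 (SD, n = 2), the difference from (+) was 1.65-fold. The median length of enriched peaks was 48 and 49 nt in ΔRRM and 52 nt without a transgene, against 31 and 28 nt in (+) and 33 and 33.5 nt in C130Y. The libraries with longer peaks had the lowest CLIP totals, at most 0.893 M against at least 1.21 M reads. Depth and form of the protein can therefore not be told apart for peak length. Both ΔRRM libraries and both C130Y libraries exceeded both (+) libraries in number, and each exact two-sided permutation p was 0.333, the smallest that 2 against 2 libraries allow. The ΔRRM and C130Y libraries overlapped in number, and the exact permutation p between them was 0.667. Thinned to equal CLIP and input totals, the libraries kept this order against (+), with means of 528 and 541 enriched peaks in (+), 720 and 702 in C130Y and 1550 and 891 in ΔRRM. Thinned further to the no-transgene totals, the means were 312 and 329 in (+), 461 and 460 in C130Y and 669 and 368 in ΔRRM. Only ΔRRM replicate 1 then stood above the 615 of the no-transgene library. The numbers of enriched peaks therefore do not separate sites of the protein from background.

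**Figure D1:**
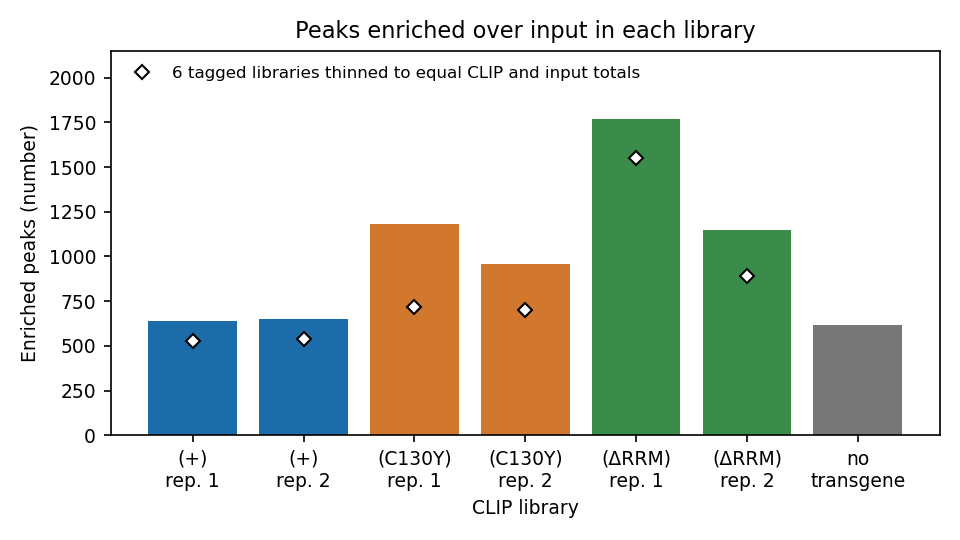
Enriched peaks (number, log2 enrichment of at least 1 and −log10 p of at least 3) in each of the 7 CLIP libraries; diamonds are means of 100 thinnings of the 6 tagged libraries to equal totals. Both ΔRRM libraries, 1767 and 1146, stand above both (+) libraries, 640 and 651, and remain above them when thinned. Thinned to the lower no-transgene totals, not drawn here, only ΔRRM replicate 1 stays above the 615 of the no-transgene library.

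The enriched peaks merged into 2738 regions, of which 257 were reproducible in (+), 461 in C130Y and 686 in ΔRRM. The share of the union found in both libraries of a genotype was 42.2% for (+), 43.4% for C130Y and 37.0% for ΔRRM. Across the reproducible regions the log2 enrichments of both libraries correlated with a Pearson r of 0.72 in (+), 0.84 in C130Y and 0.66 in ΔRRM, across regions, which are not independent replicates. The libraries of ΔRRM stood further apart than those of the other forms, with medians of 3.32 and 2.27 over its reproducible regions and a median absolute difference of 1.05 on the log2 scale, against 0.55 in (+) and 0.39 in C130Y. The order of C130Y and ΔRRM turned at a log2 enrichment of at least 3, where 159 regions were reproducible in C130Y and 136 in ΔRRM and the ΔRRM libraries had 912 and 278 enriched peaks, and at a −log10 p of at least 5 the numbers were 176 in (+), 323 in C130Y and 380 in ΔRRM.

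Libraries of 1 genotype shared more of their regions on average than libraries of different genotypes. The Jaccard index was 0.422, 0.434 and 0.370 within (+), C130Y and ΔRRM. Pairs of a (+) and a C130Y library reached 0.289 to 0.376, pairs of a C130Y and a ΔRRM library 0.211 to 0.238, and pairs of a (+) and a ΔRRM library 0.166 to 0.206. The mean within genotypes exceeded that between genotypes by 0.165, the highest of the 15 splits of the libraries into pairs, with an exact p of 0.0667, the smallest possible, and 0.0858 for the next split. At a −log10 p of at least 1.3 the difference was 0.0852. The no-transgene library had its lowest indices with the ΔRRM libraries, 0.0587 and 0.0632, against 0.122 to 0.183 with (+) and C130Y. Unequal list lengths limit the index. The lists held 441 and 425 regions in (+), 866 and 658 in C130Y, 1565 and 977 in ΔRRM and 521 without a transgene. List length can therefore hold down the values with ΔRRM and the mean between genotypes.

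**Figure D2:**
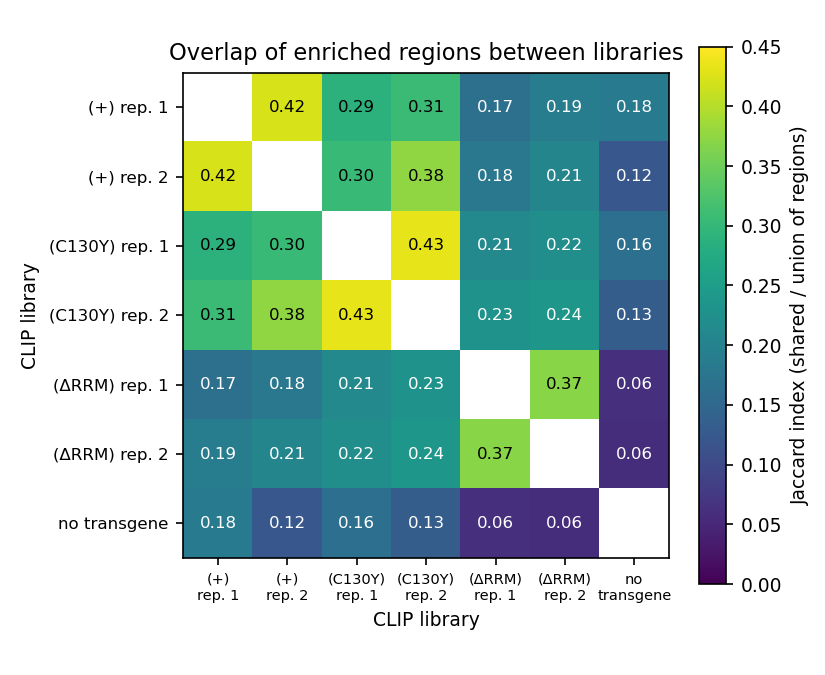
Jaccard index (shared regions over the union) of the enriched regions for each pair of the 7 CLIP libraries. Libraries of 1 genotype reach 0.37 to 0.43, libraries of different tagged genotypes 0.17 to 0.38, and the lowest values join ΔRRM with the no-transgene library (0.06). Unequal list lengths also limit the index.

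The next comparison asked which regions needed the RNA recognition motif, with the ΔRRM and no-transgene libraries as controls. Of the 257 (+) regions, 41 (16%, interval 12.0% to 20.9%) had no enriched peak in any of the 3 control libraries, in 36 loci. The leading one lay on chromosome II at 7001621 to 7001663 on the plus strand, with a log2 enrichment of 5.44 and 4.11 in the 2 (+) libraries, against listed values of 1.32 and 0.55 in ΔRRM and of 2.74, on 3 CLIP reads, without a transgene. With the abutting pieces at 7003263 to 7003270 and 7003271 to 7003286, it made a cluster of 3 such regions within 1666 nt, and the second piece had 3.45 and 5.47 in (+) and 2.88, on 5 CLIP reads, in ΔRRM replicate 2. On chromosome X, 10821281 to 10821342 on the minus strand had 4.00 and 4.17 in (+) and 1.93 and 2.14 in ΔRRM. On chromosome III, the minus-strand regions 6888547 to 6888596 (3.74 and 3.88), 11393041 to 11393153 (3.74 and 4.47) and 13523795 to 13523821 (4.42 and 3.49) followed. The abutting pieces 13748162 to 13748172 and 13748173 to 13748185 on the plus strand of chromosome I both had 3.16 and 3.24. In the mitochondrial genome, 10372 to 10399 on the plus strand had 3.85 and 3.13 and no listed peak in ΔRRM or the no-transgene library.

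Most of these 41 regions were not empty in the controls. Listed peaks with a log2 above 0 but below the thresholds lay in 33 of them, so 8 had none in any control library. In ΔRRM replicate 1 the 3 chromosome III regions each had a listed log2 of 3.51 on 4 CLIP reads and 1 input read. The (+) libraries had 18 to 41 CLIP reads and 1 to 3 input reads there. Over all 257 (+) regions, 224.4 and 234.7 would have passed at the (+) read shares and the depths of the first and second ΔRRM library, and 205 and 166 did. At the depth of the no-transgene library 137 would have passed, and 88 did. Of the 41 regions alone, 29.9 and 33.4 would have passed at the ΔRRM depths but only 8.80 at the no-transgene depth. Absence from the no-transgene library therefore says little about the 41 regions. The 257 regions were chosen for passing in both (+) libraries, which can raise these expected numbers. Of the regions enriched in 1 library of a genotype, its replicate missed 1.15 to 4.97 times as many as such simulations give. Those regions did not have to pass in both libraries, unlike the 257, so these ratios can overstate the misses due among the 257. The shortfalls over the 257 regions alone therefore neither show nor exclude a loss. Leaving out the no-transgene library changed the 41 regions to 45, and leaving out ΔRRM replicate 1 changed them to 72.

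The overlap of (+) with ΔRRM was larger than the set of regions absent from ΔRRM. Both forms shared 159 reproducible regions, 61.9% of those of (+), where independent lists would share 64.4, and 205 and 166 of the 257 (+) regions had an enriched peak in the first and second ΔRRM library. In the reverse direction, 410 of the 686 ΔRRM regions (59.8%, interval 56.1% to 63.4%) had no enriched peak in (+), in 330 loci, and 404 of these were also absent from the no-transgene library. Among the 410, 123 had an enriched peak in at least 1 C130Y library. The leading regions were 9763230 to 9763288 on the plus strand of chromosome IV, with 4.6 and 4.88 in the ΔRRM libraries and listed values of 1.78 and 0.88 in (+), and 12124711 to 12124757 on the same strand, with 4.83 and 4.25. On chromosome III the plus-strand regions 8911388 to 8911558 (4.21 and 4.46) and 13073822 to 13073913 (4.97 and 3.88) were among them, and the former had a listed value of 3.51 in (+) replicate 1, on 17 CLIP reads and 1 input read. On chromosome X they were joined by 9091305 to 9091335 (4.97 and 4.01) and 12692430 to 12692536 (3.83 and 4.55) on the plus strand and by 767067 to 767208 (4.02 and 3.68) on the minus strand, and the region at 12692430 had a listed value of 2.71 in (+) replicate 2. Chromosome V held 11602038 to 11602093 (4.32 and 4.14), chromosome II 9333600 to 9333744 (4.21 and 3.64) and chromosome IV 11926532 to 11926620 (3.73 and 3.88), all on the plus strand. These calls rested on 7 to 57 CLIP reads and 1 to 10 input reads per library. In (+), 355 of the 410 regions had a listed peak with a log2 above 0, which left 55 without one, and without ΔRRM replicate 2 the count was 1181.

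**Figure D3:**
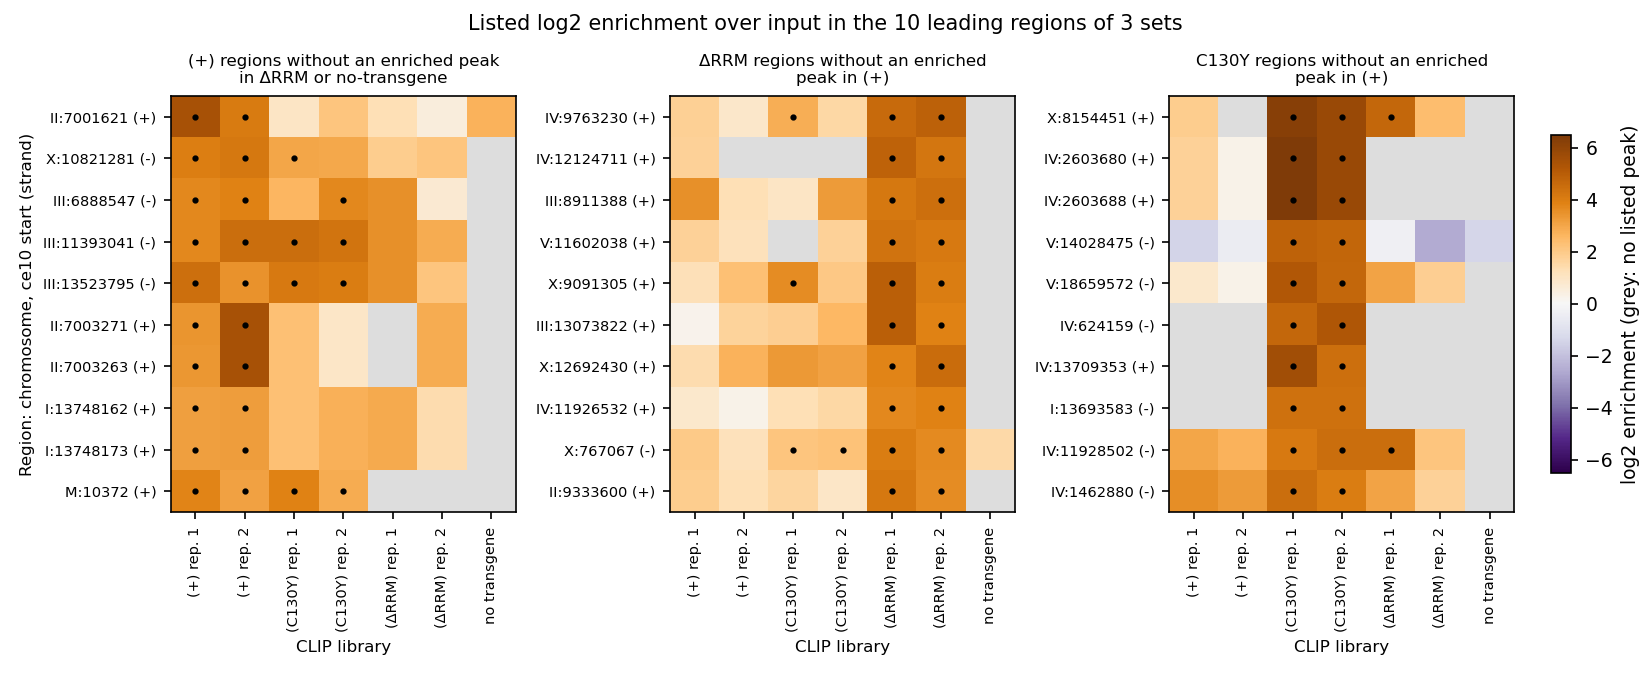
Listed log2 enrichment over input (colour) of the 10 leading regions of each of 3 sets (rows, by chromosome and ce10 start) in the 7 CLIP libraries (columns); dots mark enriched peaks and grey marks regions with no listed peak. The chromosome V region at 14028475 has 4.86 and 4.75 in the C130Y libraries and lies below 0 in all others.

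The last comparison between genotypes asked whether C130Y changed where the protein was crosslinked. The 2 forms shared 194 reproducible regions, 75.5% of those of (+) (interval 69.9% to 80.3%) and 42.1% of those of C130Y, where independent lists would share 43.3. Of the shared regions, 13 were absent from ΔRRM and the no-transgene library. Most of the 10 leading ones held listed ΔRRM peaks with a log2 above 0 that missed the thresholds. They included 11393041 to 11393153 on chromosome III, with 4.49 and 4.28 in C130Y and listed values of 3.51 and 2.88 in ΔRRM. Also among them was 13523795 to 13523821, with 4.12 and 4.04 in C130Y and listed values of 3.51 and 2.14 in ΔRRM. A further region on the same strand, 11389587 to 11389691, formed a locus of 3567 nt with the first. It had 2.86 and 3.27 in (+), 2.44 and 3.37 in C130Y and listed values of 2.10 and 1.14 in ΔRRM. On chromosome I, 13161100 to 13161131 had 3.12 and 4.30 in (+) and 3.02 and 4.41 in C130Y, and 9605786 to 9605833 had 3.42 and 2.96 in (+) and 3.90 and 2.69 in C130Y, both on the plus strand. In ΔRRM the former had listed values of 2.19 and 1.69, and the latter had 4.10, on 6 CLIP reads, and 1.23. On the plus strand of chromosome V, 17428885 to 17428907 had 648 and 472 CLIP reads in (+) and 497 and 868 in C130Y, with no listed peak in ΔRRM and a log2 of 0.66 without a transgene. The mitochondrial region at 10372 had 3.90 and 2.86 in C130Y and no listed peak in ΔRRM or the no-transgene library.

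C130Y regions absent from (+) outnumbered the reverse. There were 158 of the former, 34.3% of the C130Y regions (interval 30.1% to 38.7%), and 31 of the latter, 12.1% of the (+) regions (interval 8.63% to 16.6%). The C130Y list was longer, 461 reproducible regions against 257, which favours this direction. With reads thinned to equal totals, the mean numbers were 114 and 33.2. The 158 regions included 8154451 to 8154485 on the plus strand of chromosome X, with 6.27 and 5.81 in C130Y and 4.68 in ΔRRM replicate 1, and the abutting pieces 2603680 to 2603687 and 2603688 to 2603702 on the plus strand of chromosome IV, with 6.82 and 5.80 and 181 and 115 CLIP reads. The minus-strand region 14028475 to 14028517 on chromosome V had 4.86 and 4.75 in C130Y on 583 and 945 CLIP reads, and its listed values were −1.46 and −0.51 in (+), −0.33 and −2.54 in ΔRRM and −1.39 without a transgene. No listed peak in any other library lay in 624159 to 624165 on the minus strand of chromosome IV (4.69 and 5.24 in C130Y), in 13709353 to 13709389 on its plus strand (5.59 and 4.42) or in 13693583 to 13693606 on the minus strand of chromosome I (4.38 and 4.41). By contrast, 11928502 to 11928535 and 1462880 to 1462935 on the minus strand of chromosome IV had listed log2 values of 2.71 to 3.59 in (+) and missed the p minimum there. A ΔRRM library had an enriched peak in 76 of the 158 regions.

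The 31 (+) regions absent from C130Y were led by 8624286 to 8624305 on the plus strand of chromosome X, with 4.33 and 4.14 in (+), listed values of 2.73 and 2.66 in C130Y and enriched peaks of 5.10 and 2.62 in ΔRRM. A ΔRRM library had an enriched peak in 13 of the 31 regions. The chromosome II cluster from 7001621 to 7003286 was also among them, with listed C130Y values of 1.00 and 2.18 at its first region. On the minus strand of chromosome X, 4677990 to 4678074 had 3.04 and 3.17 in (+), 2.76 in 1 C130Y library and no listed peak elsewhere. On chromosome II, 7666188 to 7666215 had 3.74 and 3.01 in (+) and 1.32 and −0.89 in C130Y. In 28 of the 31 regions a C130Y library had a listed peak with a log2 above 0, and of the 158 regions absent from (+) this held for 122 in a (+) library. Leaving out (+) replicate 2 raised the 31 to 120, and leaving out C130Y replicate 2 raised the 158 to 482.

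The no-transgene library, with 0.192 M CLIP reads, was used to describe the background. It had an enriched peak in 88 of the 257 (+) regions (34.2%), in 135 of the 461 C130Y regions (29.3%) and in 76 of the 686 ΔRRM regions (11.1%). At its depth 137 of the 257 (+) regions would have passed, so these shares can understate the background. No such expected number is given here for the C130Y or ΔRRM regions. Of the 136 regions reproducible in all 3 tagged forms, 65 were also enriched without a transgene and 71 were not. Chromosome X held 21 of the 615 enriched peaks of the no-transgene library (3.41%, Wilson interval 2.24% to 5.16%). In the 6 tagged libraries it held 9.74% to 12.9%, and the lowest of their intervals began at 8.17%. The share was 11.8% ± 1.5 in (+), 10.6% ± 1.16 in C130Y and 12.5% ± 0.122 in ΔRRM (SD, n = 2 each, exact permutation p of 0.667 for C130Y and 1 for ΔRRM against (+)). Both ΔRRM libraries lay above both C130Y libraries, with an exact permutation p of 0.333, the smallest possible. The control is a single library, so its difference from the tagged libraries has no replicate check, and at its read totals the tagged libraries had 3.35% to 11.9%.

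**Figure D4:**
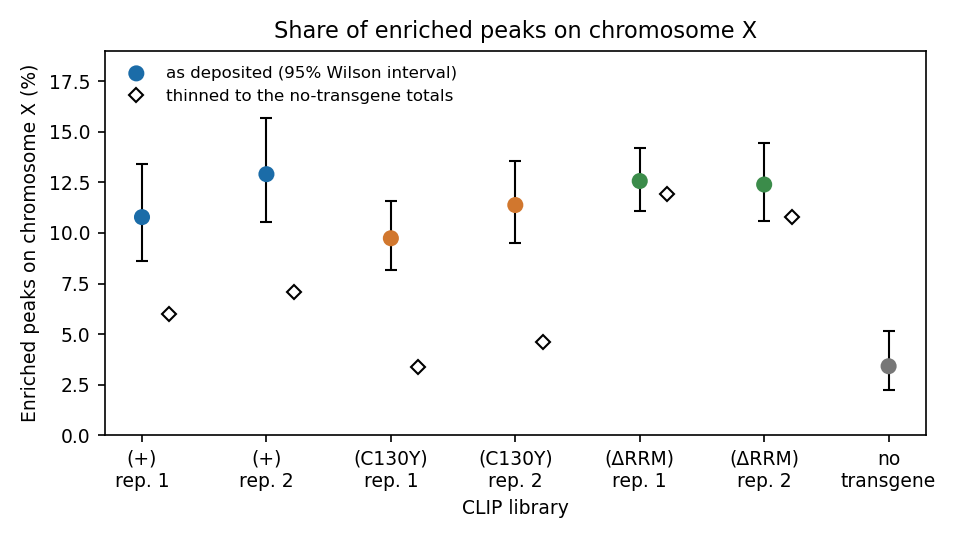
Percent of enriched peaks on chromosome X in the 7 CLIP libraries, with 95% Wilson intervals; diamonds are the means of 100 thinnings of the tagged libraries to the no-transgene totals. The no-transgene library has 3.41% and the tagged libraries 9.74% to 12.9%, and thinned C130Y libraries fall to 3.35% and 4.61%.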

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

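Of 140 values under other settings, 44 were counts more than 1.5 times off or chromosome X differences off by more than 1 SD, and 0 ratios, similarities or chromosome X differences changed sign. The log2 ratios of enriched peaks and the library similarity were judged by direction, as these designs cannot pass a threshold. They ranged from 0.80 to 1.69 for ΔRRM over (+) and from 0.41, with thinned reads, to 1.13 for C130Y over (+), and the similarity difference from 0.0852, at a −log10 p of at least 1.3, to 0.197. The settings with thinned reads, joined abutting pieces, no no-transgene library and the chromosome X share were chosen after seeing the data. At a log2 of at least 3, reproducible regions were 85 in (+), 159 in C130Y and 136 in ΔRRM, which turned the order of the latter 2. The (+) regions absent from ΔRRM and no-transgene were then 22, the ΔRRM regions absent from (+) 83, those shared by (+) and C130Y 58, those of (+) absent from C130Y 16 and the reverse 75. At a −log10 p of at least 5, reproducible ΔRRM regions were 380, the (+) regions absent from ΔRRM and no-transgene 23, the ΔRRM regions absent from (+) 218 and the (+) regions absent from C130Y 20. At a −log10 p of at least 1.3, reproducible regions were 476, 873 and 1521, the (+) regions absent from ΔRRM and no-transgene 74, the ΔRRM regions absent from (+) 925, those shared by (+) and C130Y 337, those of (+) absent from C130Y 57 and the reverse 313. With absence meaning no listed peak with a log2 above 0, these sets of absent regions were 8, 55, 3 and 36. Without regions also in ΔRRM or no-transgene, 13 were shared, 18 were absent from C130Y and 63 from (+). The chromosome X share of the tagged libraries exceeded that of the no-transgene library by 8.21 percentage points, by 4.93 at a −log10 p of at least 1.3 and by 3.89 with thinned reads. The cause of these changes was not tested.

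When a library was left out, presence rested on 1 library of its genotype or absence was asked of fewer libraries, and both raise the counts by construction. Reproducible regions were 425 to 441 in (+), 658 to 866 in C130Y and 977 to 1565 in ΔRRM. The (+) regions absent from ΔRRM and no-transgene were 46 to 93, with 93 and 89 without (+) replicate 1 and 2 and 72 without ΔRRM replicate 1. The ΔRRM regions absent from (+) were 462 to 1181, with 677 and 1181 without ΔRRM replicate 1 and 2. The (+) regions absent from C130Y were 47 to 120, with 95 and 120 without (+) replicate 1 and 2 and 47 without either C130Y library. The C130Y regions absent from (+) were 194 to 482, with 314 and 482 without C130Y replicate 1 and 2, and 210 to 267 were shared. The log2 ratio of enriched peaks was 0.83 to 1.45 for ΔRRM and 0.57 to 0.87 for C130Y over (+). Of the 50 named entries, 20 stayed in their set at a −log10 p of at least 1.3, 30 at 5, 41 at a log2 of at least 3, 32 at an overlap of 20 nt and 6 with the stricter meaning of absence.

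The replicate differences of 2 genotypes correlated at 0.027, −0.14 and 0.0017 across 2880 regions, which gave no sign that replicate numbers pair the libraries. This check used log2 values only, so a shared batch acting on depth or on the number of peaks would not appear in it. With the replicate block the log2 ratios stayed 1.14 and 0.72, with an exact sign-flip p of 0.5, the smallest possible. Peak features by midpoint and gene lists from either replicate were not run because the annotation was of another build. Depth limited calls of absence, since 137 of the 257 (+) regions would pass at the no-transgene depth.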

Other observations

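Of the tests of explanations in this part, 2 were chosen only after the result was seen. They are the test of listed peaks on chromosome X and the comparison of ΔRRM with the no-transgene library at equal depth.

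Chromosome X held different shares of the regions by their presence in the no-transgene library, whose own share on X was low, and these shares were not tested. Of the 71 regions reproducible in (+), C130Y and ΔRRM and absent from the no-transgene library, 15 (21.1%) lay on chromosome X, and of the 65 regions enriched in all 7 libraries 2 (3.08%) did. Among the no-transgene regions, 8 of the 236 shared with a tagged library (3.39%, interval 1.73% to 6.55%) and 13 of the 285 found in no tagged library (4.56%, interval 2.68% to 7.65%) were on X, against 292 of the 2217 regions found in tagged libraries only (13.2%, interval 11.8% to 14.6%). The mitochondrial genome held 43 and 31 enriched peaks in the ΔRRM libraries, 19 and 10 in (+), 15 and 17 in C130Y and 6 in the no-transgene library. These were 2.43% and 2.71%, 2.97% and 1.54%, 1.27% and 1.77%, and 0.976% of the enriched peaks, and the share in ΔRRM did not differ from that in (+) by more than the spread between libraries (exact permutation p of 1, n = 2 each). Both ΔRRM libraries lay above both C130Y libraries in this share, 2.57% against 1.52% on average, with an exact permutation p of 0.333, the smallest possible.

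The larger number of enriched peaks in ΔRRM than in (+), despite the loss of the RNA recognition motif, was set against the difference in read depth. With all tagged libraries thinned to the same totals, the lower ΔRRM library exceeded the higher (+) library in 100 of 100 thinnings, and the log2 ratio was 1.14 before and after, which argues against CLIP and input depth as the whole cause at the deposited peak positions. The thinning could move such a ratio, since that of C130Y over (+) fell from 0.72 to 0.41. The excess was also set against a few dominant sites in (+). Without the 50 peaks of most recovered CLIP reads in each library, the ratio of the means was 2.47. The excess thus remained without the recovered reads of these peaks. Read numbers at the cap are lower bounds, and the removal moved log2 values by only 0.09 and 0.11 in the (+) libraries. Dominant sites can therefore not be excluded by this test. An effect of depth on where peaks were called stays open, because peaks were not called anew, as do differences in RNA digestion or immunoprecipitation and the untested candidate explanation that crosslinking without the motif was spread over more RNA.

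The low share of chromosome X in the no-transgene library, 3.41%, was not due to fewer listed peaks there, since 10.0% of all its listed peaks lay on X, inside the range of the tagged lists of 9.87% to 11.9%. Depth cannot be told apart as a cause against C130Y, with 3.35% and 4.61% at the no-transgene totals, or against (+), whose means of 6.02% and 7.11% lay above the no-transgene upper bound of 5.16% while single thinnings fell to 3.37% and 4.86%. Against ΔRRM, read depth at the deposited peak positions does not account for it, since the lower thinned ΔRRM library had 10.8% and its lowest thinning 9.20%. Whether depth changed which peaks were called stays open here too, because peaks were not called anew. Chromosome X carries few genes active in the germline, as background, and RNA of motor neurons in the tagged worms against RNA of the whole worm without a tag may therefore underlie part of the difference. This hypothesis was not tested, and the strain background differed too.

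The 41 (+) regions with no enriched peak in ΔRRM or no-transgene were set against missed calls at the depth of those libraries. Simulated from the (+) read shares, 8.48 regions would be missed in all 3 on average, and 14 at the upper end of the central 95% of simulations. Of the regions enriched in 1 library of a genotype, its replicate missed 1.15 to 4.97 times as many as such simulations give, 2.92 times on average. Scaling the upper end by that average gives 40.9, which lies below 41 by less than the spread of the ratios. The ratios are for misses in 1 library, among regions that did not have to pass in both replicates. Joint misses in 3 libraries need not scale by the same factor, so 40.9 is not a firm bound. Missed calls and a need for the motif can therefore not be told apart. The requirement that the bound hold over that spread was set after the value was seen. Of the 41 regions, 8 had no listed peak above 0 in any control library.

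The 50 peaks of most recovered CLIP reads took 29.8% of the CLIP reads of the no-transgene library and 10.9% to 14.8% of those of the tagged libraries. Reads of peaks at the cap enter these shares as lower bounds.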
